A study of Mus musculus with 2 samples.

How the data were processed

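Total RNA from the mouse embryonic stem (ES) cell line R1 was measured on 2 one-colour Agilent expression arrays, 1 from undifferentiated ES cells (day 0) and 1 from embryoid body cells at day 6 of neural differentiation. Per the labels, the RNA was extracted with Trizol, purified on Qiagen columns and labelled with Cy3. Per the labels, the ES cells were grown on mitotically inactive fibroblast feeders with 15% fetal bovine serum and leukaemia inhibitory factor (LIF) at 1000 U/ml. How feeder cells were removed before RNA extraction is not given in the sources used here.

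Per the file headers, both arrays had the 014868 design, were read in 1 channel and were extracted with Feature Extraction 9.5.3.1 with extended dynamic range, spatial detrending and multiplicative detrending. The deposited scanner files give, per spot, an intensity after the software's background subtraction and detrending, the software's error of that intensity, the mean intensity before background subtraction and the median intensity of the local background. Per the file headers, spots not above background carry a surrogate value in place of a subtracted intensity, and the software marks spots well above background, saturated spots and outliers. Both arrays lay on the same slide and were read in the same scan, at different positions, so position and group cannot be told apart. The headers name the mouse genome build mm7 (NCBI build 35), and probe positions are given in that build.

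The authors also deposited a value table on a log2 scale. Its sorted columns differed by at most 0.000469, so the distributions of the 2 arrays had been made equal, and the median was 8.53 in both columns. The differences in this table and those from the scanner files had a Pearson correlation of 0.989 across probes, which are not independent replicates. The steps that made the table are not given in the sources used here. Its log base and its day 6 minus day 0 direction were settled by this comparison, and it was used as an alternative. Of its 41252 probes, 78 were not gene probes of the scanner files and were not used.

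Each array held 45018 spots, of which 43379 were for 41174 gene probes. Control spots and outlier spots were left out (186 on day 0 and 216 on day 6), the log2 intensities of spots of the same probe were averaged, and the 75th percentile of the array was subtracted. That percentile was 3746 intensity units on day 0 and 4371 on day 6. Saturated spots were kept. A probe was used where it was well above background on at least 1 array. On day 0, 25246 probes (61.4%) were well above background and 9 were saturated. On day 6, 26896 (65.4%) were well above background and 5 were saturated. The lowest intensity among probes well above background was 102 on day 0 and 85.2 on day 6.

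Probes were named through a RefSeq gene table of assembly GRCm38.p6, used for names only. The accession in the scanner file named 22951 probes, a current symbol named 6659 and an older symbol belonging to 1 gene named 3109. The remaining 8455 probes had no symbol and were not used for genes. Of 19505 symbols, 14967 genes had a probe well above background on at least 1 array. Each was given the value of its probe with the highest mean log2 intensity. Of 6528 genes with several such probes, 59 had probes at least 2-fold higher and at least 2-fold lower, and 0 of these were among the 140 genes chosen by the rule below. List members can be among the 59, as were Ncam1 and Slc1a3 of the neural progenitor list, named here outside that rule.

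Each group had 1 array, so no test, p-value or standard error between conditions was possible, and every difference has no replicate check. Genes were counted by the size of the day 6 minus day 0 difference, at 2-fold and at 4-fold. For a gene well above background on only 1 array the fold is a lower bound, written "at least". It sets the bright array's normalized value against the dim array's, taken as the higher of the lowest value well above background on that array and the probe's own value. Technical error is given in 2 ways. The software's error model, with a multiplicative error set at 0.1, gave a median SD of 0.20 log2 units for a difference. For bright probes this SD follows from that setting and is not an estimate from these arrays. Among probes spotted 10 times, the median SD between spots of a probe was 0.0532 log2 units on day 0 (171 probes) and 0.0449 on day 6 (179 probes). Neither holds the variation between cultures, and the number of arrays limits the precision.

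A total of 29 gene lists (9 main and 20 other) were fixed before the data were examined, from textbook knowledge of ES cell differentiation and of other cell types the cultures could hold. The main lists were pluripotency, primed epiblast, neural progenitor, forebrain and eye field, midbrain, hindbrain and spinal cord, neuronal, primitive streak and mesoderm, endoderm, and feeder fibroblast. Each list's median log2 difference is given relative to the median of all 14967 genes, which was -0.09. It was placed among the medians of 10000 random lists of the same size, matched on 20 bins of mean log2 intensity, as a description of these 2 arrays. Lists outside the 2.5 to 97.5 percentile band are said to lie outside it. The genes named were 14 fixed markers, the 12 genes with the largest positive and the 12 with the largest negative difference among genes well above background and unsaturated on both arrays (clone-like and unnamed loci left out), and up to 4 members of each list with the largest difference or bound. Some genes that the rule takes are not reported here. Genes named outside this rule are said to be so.

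The alternatives were median scaling, quantile normalization, normexp background correction (offset 50), no background subtraction, the deposited log2 table, a filter on both arrays, no filter, the mean of a gene's probes, outlier spots kept, saturated probes left out, probes in place of genes, unmatched random lists, lists without their most different member, and dim members set at their bound. The procedure was tested on simulated data. A copy of the day 0 array with noise from the software's error model gave 13793 genes. Of 100 genes planted at 4-fold and 100 planted at 2.83-fold, 100% were recovered at 2-fold for each size, and 1 of 13593 unchanged genes passed 2-fold. Both planted sizes lay above the cut, so the recovery mainly checks the code. The copy held no second array, labelling or culture, so these results give no error rate for the real counts. All planted genes were brighter than the median gene on day 0, and the copy kept the day 0 background marks. No simulated gene was therefore counted by a bound, and the simulation does not describe such genes. Of 200 random lists of 20 genes drawn from the real differences, 5% fell outside the band. That share follows from the definition of the band and checks only the code.

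Across probes, GC content and the log2 difference had a Spearman correlation of -0.10. Blocks of 38 by 17 spots explained 0.378% of the variance of the difference, against 0.289% with shuffled positions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.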

Results

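Gene expression was measured in the mouse ES cell line R1 before (day 0) and after 6 days of direct neural differentiation as embryoid bodies, which are floating cell aggregates. The labels describe the day 6 cells as neural precursors. Each group held 1 array, so the differences below have no replicate check and describe these 2 RNA samples. The software error of a difference was 0.20 log2 units at the median. Among probes well above background on both arrays, log2 intensities of the 2 arrays had a Pearson correlation of 0.885 across probes.

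The comparison asks which genes differ between ES cells and their neural derivatives. Day 0 cells grew on feeders with serum and LIF, and the LIF and serum levels of day 6 are not stated here. Differences from medium, feeders or aggregation therefore cannot be told apart from differentiation. Pluripotency genes were much lower on day 6, and genes of neural progenitors, forebrain and neurons were higher. Of 14967 genes, 2662 (17.8%) were at least 2-fold higher on day 6 and 3002 (20.1%) at least 2-fold lower. At 4-fold, 1100 were higher and 1249 lower. Of the genes counted at 2-fold, 531 of the higher and 663 of the lower ones were counted by a bound, because they were well above background on 1 array only.

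**Figure D1:**
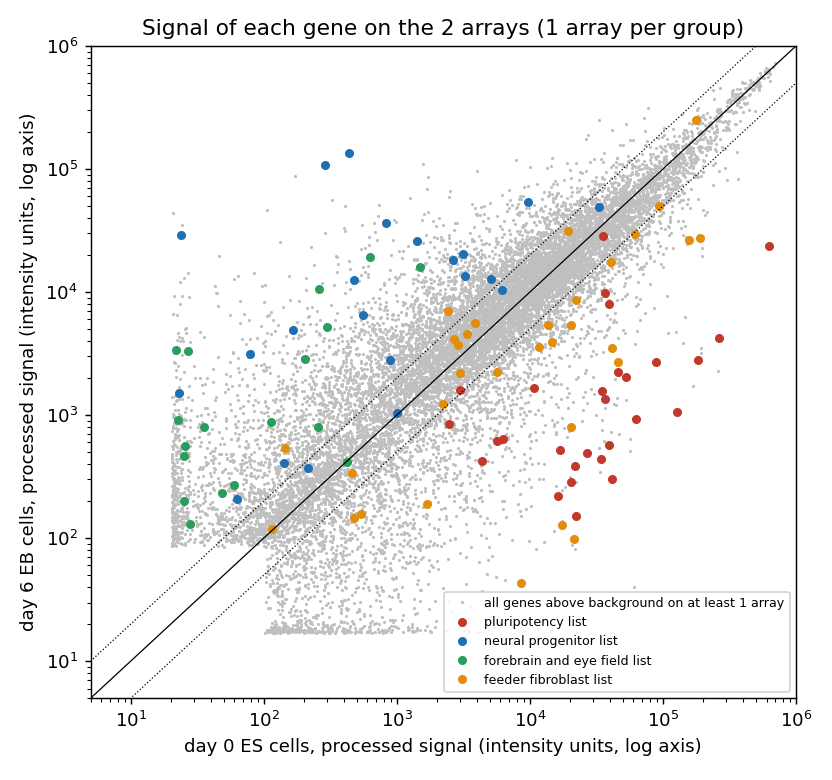
Processed signal of each gene on the day 0 array (x axis) and the day 6 array (y axis), both in intensity units on log axes, with 1 array per group. Grey points are the 14967 genes, coloured points are members of 4 lists, the solid line marks equal signal and the dotted lines mark 2-fold differences before scaling. Most pluripotency genes lie below the lines and most neural progenitor and forebrain genes above them.

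The pluripotency list was the lowest of the main lists on day 6. Of its 28 measured members, 27 were at least 2-fold lower and 0 were higher, and the list median was -5.02 log2 units (32.4-fold lower), below the random band of -0.40 to 0.49. Pou5f1 (Oct4), a core pluripotency transcription factor, had an intensity of 41679 on day 0 and 302 on day 6, a log2 difference of -7.33 ± 0.22 (software error SD). Its probe, for accession NM_013633, lies at chromosome 17, 33612047 to 33612107. Nanog was 63.5-fold lower, Zfp42 (Rex1) 72.1-fold lower and Esrrb 90.3-fold lower. The Nodal co-receptor gene Tdgf1 was 172-fold lower, and Dnmt3l, a cofactor of DNA methyltransferases, was 141-fold lower. Sox2, a factor of both ES cells and neural progenitors, had intensities of 66002 and 57172, a log2 difference of -0.43 ± 0.20.

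Genes of the primed epiblast, the state that follows naive pluripotency, were also mostly lower. Of 16 measured members, 13 were at least 2-fold lower and 2 at least 2-fold higher, with a median of -2.95. Fgf5 was 9.43-fold lower, Nodal 54.3-fold lower and Lefty2, an inhibitor of Nodal signalling, 175-fold lower. Otx2, a gene of both epiblast and anterior neural tissue, was 2.89-fold higher (log2 difference 1.53 ± 0.20). The median stood at -1.83 when only members well above background on both arrays were used.

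Neural progenitor genes were at least 2-fold higher on day 6 in 17 of 22 measured members and lower in 0. The list median was 2.62 (6.14-fold), above the random band of -0.51 to 0.67. Fabp7 (BLBP), a radial glia fatty acid binding protein, was 319-fold higher, from 291 to 108342 intensity units. Hes5, a Notch effector, was 268-fold higher, with its probe for NM_010419 at chromosome 4, 153951780 to 153951839. Dbx1, a homeobox gene of the neural tube, was not well above background on day 0 and was at least 246-fold higher on day 6. Pax6 was 5.60-fold higher, and Sox1 2.45-fold higher with low intensities on both arrays (142 and 406). Nes, the gene of the progenitor filament nestin, was 1.26-fold higher, with a log2 difference of 0.34 ± 0.20.

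Forebrain and eye field genes were at least 2-fold higher in 14 of 18 measured members and lower in 0. The list median was 3.84 (14.3-fold), above the band of -0.78 to 1.03. It stood at 2.83 with dim members at their bound and at 2.28 with no background subtraction. The LIM homeobox genes Lhx2 and Lhx5 were 26.3-fold and 34.7-fold higher. Fezf2 and Fezf1 were not well above background on day 0 and were at least 28.1-fold and 27.7-fold higher on day 6. Six3, Six6 and Hesx1, named here outside the fixed rule, were not well above background on either array. Genes of the midbrain, hindbrain and spinal cord differed in both directions. Of 18 measured members, 6 were at least 2-fold higher and 4 at least 2-fold lower, with a median of 0.84 inside the random band of -0.72 to 0.99. Hoxb2 was 35.0-fold higher and Hoxa2 at least 76.2-fold higher, while the posterior gene Hoxb9 was 24.5-fold lower. Hoxb9 had 1858 intensity units on day 0 and 88.7 on day 6, near the lowest signal well above background (85.2). Whether its day 0 signal came from ES cells or feeder cells was not tested. The median of the midbrain, hindbrain and spinal cord list was -0.62 when only members well above background on both arrays were used. It lay above the band with members at their bound (percentile 97.6) and against unmatched random lists (percentile 99.1).

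Neuronal genes were at least 2-fold higher in 21 of 27 measured members and lower in 0, with a median of 2.88 (7.35-fold), which stood at 2.01 when only members well above background on both arrays were used. Elavl4 (HuD), a neuronal RNA binding protein, was 59.2-fold higher, from 1573 to 108798 intensity units. The transcription factor genes Nhlh1 and Isl1 were at least 108-fold and at least 106-fold higher. Dcx (doublecortin), a microtubule protein of migrating neurons, was at least 93.5-fold higher.

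**Figure D2:**
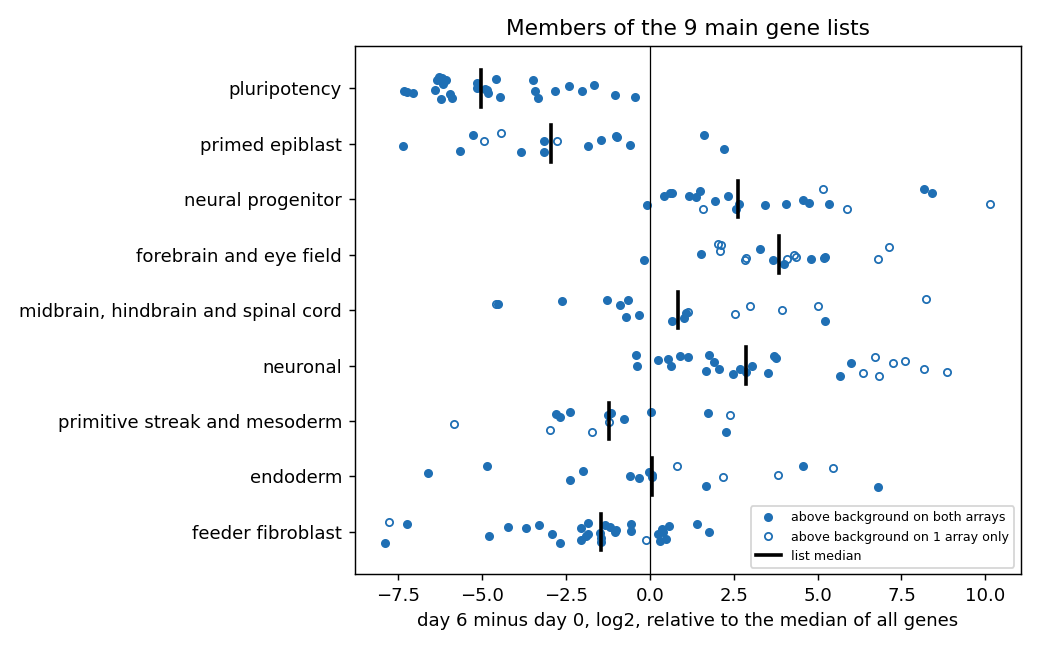
Log2 difference, day 6 minus day 0, relative to the median of all genes (x axis, log2 units), for members of the 9 main lists (y axis; vertical scatter within a list has no meaning). Filled points are well above background on both arrays and open points on 1 array only. Open points are not bounds: they use the dim array's own value, which can be a surrogate. Black bars are list medians, which run from -5.02 for pluripotency to 3.84 for forebrain and eye field.

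Markers of other germ layers were mixed. Of 14 measured primitive streak and mesoderm genes, 8 were at least 2-fold lower and 2 at least 2-fold higher, with a median of -1.22, below the band of -0.84 to 1.22. Wnt3 was 7.45-fold lower and Hand1 at least 13.4-fold lower. T (brachyury) had intensities of 4913 and 5525, a log2 difference of -0.05 ± 0.20. Of 16 measured endoderm genes, 6 were at least 2-fold higher and 4 at least 2-fold lower, with a median of 0.05 inside the band. Foxa2, expressed in endoderm and in the floor plate of the neural tube, was 105-fold higher, and Foxa1 at least 22.7-fold higher. Sox17 had a log2 difference of 1.58 ± 0.23. Gata4 was well above background on day 6 only (141 intensity units), at least 1.18-fold higher. Lefty1 was 104-fold lower, from 56877 intensity units on day 0 to 636 on day 6, so its fall alone is no measure of endoderm.

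Fibroblast genes, included because the ES cells were grown on feeders, were at least 2-fold lower on day 6 in 21 of 32 measured members and at least 2-fold higher in 2. The median was -1.46 (2.75-fold lower), below the band of -0.40 to 0.43. S100a4 was 159-fold lower and Thy1 29.7-fold lower. Col1a1, a fibrillar collagen gene, had intensities of 46258 and 2701 (log2 difference -4.32 ± 0.20). Lox, a collagen cross-linking enzyme, was at least 118-fold lower.

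Among the largest differences on both arrays, Igfbp5, an insulin-like growth factor binding protein, was 438-fold higher on day 6. Ctnna2 (alpha-N-catenin) was 164-fold higher, Ildr2 147-fold higher and Nkx6-1, a ventral neural tube factor, 89.2-fold higher. Lrrn1, Fgfbp3 and Rufy3 were 70.6-fold, 65.9-fold and 59.4-fold higher. These folds are of each gene's brightest probe. A second probe, also well above background on both arrays, gave log2 differences of 1.77 for Ildr2 and 2.85 for Rufy3, where the brightest gave 7.20 and 5.89. Second probes of Igfbp5 and Fgfbp3 were well above background on day 6 only and gave log2 bounds of 2.93 and 3.87. Further probes of Ctnna2, also well above background on day 6 only, gave log2 bounds of 6.60 and 1.68. Of 25 genes of the naming rule with several probes well above background on both arrays, 3 had such probes over 2 log2 units apart: Ildr2, Rufy3 and Lss. In the other direction, Pla2g1b was 155-fold lower, Tdh (threonine dehydrogenase) 132-fold lower, Zfp296 131-fold lower and Igfbp7 114-fold lower.

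Several of the 20 other lists lay above the random band. Notch pathway genes were at least 2-fold higher in 10 of 14 measured members. Their median was 1.82 (1.43 with members at their bound), and Nrarp and Dll1 were 11.6-fold and 6.77-fold higher. Hedgehog pathway genes had a median of 1.78, with 6 of 10 at least 2-fold higher and 1 lower, and the ligand gene Shh was at least 100-fold higher. Cholesterol synthesis genes were at least 2-fold higher in 13 of 22 members and lower in 0, with a median of 1.30. Cyp51 and Msmo1 were 4.42-fold and 4.26-fold higher. Lss had a log2 difference of 3.33 by its brightest probe, and its other probes gave log2 differences of 0.78 and 0.74. Imprinted genes had a median of 1.27, with 10 of 20 at least 2-fold higher and 4 lower, and Nnat was 8.49-fold higher and Phlda2 9.43-fold lower. The imprinted median was 0.80, still above the band, without the member that changed most. Glycolysis and hypoxia genes had a median of 0.70, with 8 of 24 at least 2-fold higher and 0 lower, and Bnip3 and Vegfa were 6.76-fold and 6.49-fold higher.

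Other lists lay below the band. Germline and 2-cell genes were at least 2-fold lower in 16 of 16 measured members, with a median of -4.65. That median stood at -3.93 with members at their bound and at -3.16 with no background subtraction. Zscan4c was 121-fold lower and Ddx4 (Vasa) 27.4-fold lower, and whether the Zscan4c probe separates near-identical gene copies was not examined. LIF and STAT3 genes were at least 2-fold lower in 10 of 11 members with a median of -2.12. Bcl3 was 147-fold lower and Junb 6.67-fold lower. Epithelial junction and keratin genes were at least 2-fold lower in 10 of 12, with a median of -1.97, and E-cadherin (Cdh1) was 13.4-fold lower. Trophoblast genes had a median of -1.50, with 7 of 11 at least 2-fold lower and 1 higher, but the median lay inside the band at -0.26 when only members well above background on both arrays were used, at -0.74 with normexp and at -0.71 with no background subtraction. Tfap2c was 19.3-fold lower and Cdx2 at least 47.9-fold lower.

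The remaining lists lay inside the band in the main setting. Against unmatched random lists, glia lay above it (percentile 99.0) and blood and endothelium below it (2.06). With normexp, cell cycle lay below it (percentile 2.38). Cell cycle genes had a median of -0.46 (percentile 3.25), with 3 of 25 at least 2-fold lower and Ccne1 5.72-fold lower. Retinoic acid genes had a median of 0.34, with 6 of 13 at least 2-fold higher and 4 lower, and Cyp26b1, an enzyme that breaks down retinoic acid, was 75.2-fold higher and Crabp1 34.7-fold higher. Wnt pathway genes had a median of 0.70, with 6 of 14 at least 2-fold higher and 2 lower, and a median of 3.03, above the band of that setting, when only members well above background on both arrays were used. The secreted inhibitor gene Dkk1 had a log2 difference of 4.65 ± 0.22, and Notum was at least 20.8-fold lower. The medians were -0.09 for BMP response (-0.67 to 0.44 under the alternatives), where Bmp4 was 11.2-fold lower and Id4 8.82-fold higher, and -0.31 for chromatin regulators, where 5 of 16 were at least 2-fold lower and 2 higher, Tet1 was 7.29-fold lower and Smarca2 7.66-fold higher. The glia list had a median of 1.17 over 10 members (0.31 with members at their bound), with Olig2 at least 3.23-fold higher and Cspg4 4.03-fold lower. Surface ectoderm and neural crest genes had a median of -0.10, blood and endothelium genes -0.74, muscle genes 0.04, and stress response genes -0.28. In the blood and endothelium list 3 of 13 were at least 2-fold higher and 6 lower. Tek and Pecam1, listed as endothelial genes, were well above background on day 0 only and were at least 12.3-fold and at least 9.59-fold lower. Which day 0 cells gave their signal was not tested. The embryonic globin genes Hbb-bh1 and Hba-x were at least 16.9-fold and at least 13.0-fold higher. The reference genes had a median of -0.08, with 12 of 14 within 2-fold, but Hprt was 4.42-fold lower.

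**Figure D3:**
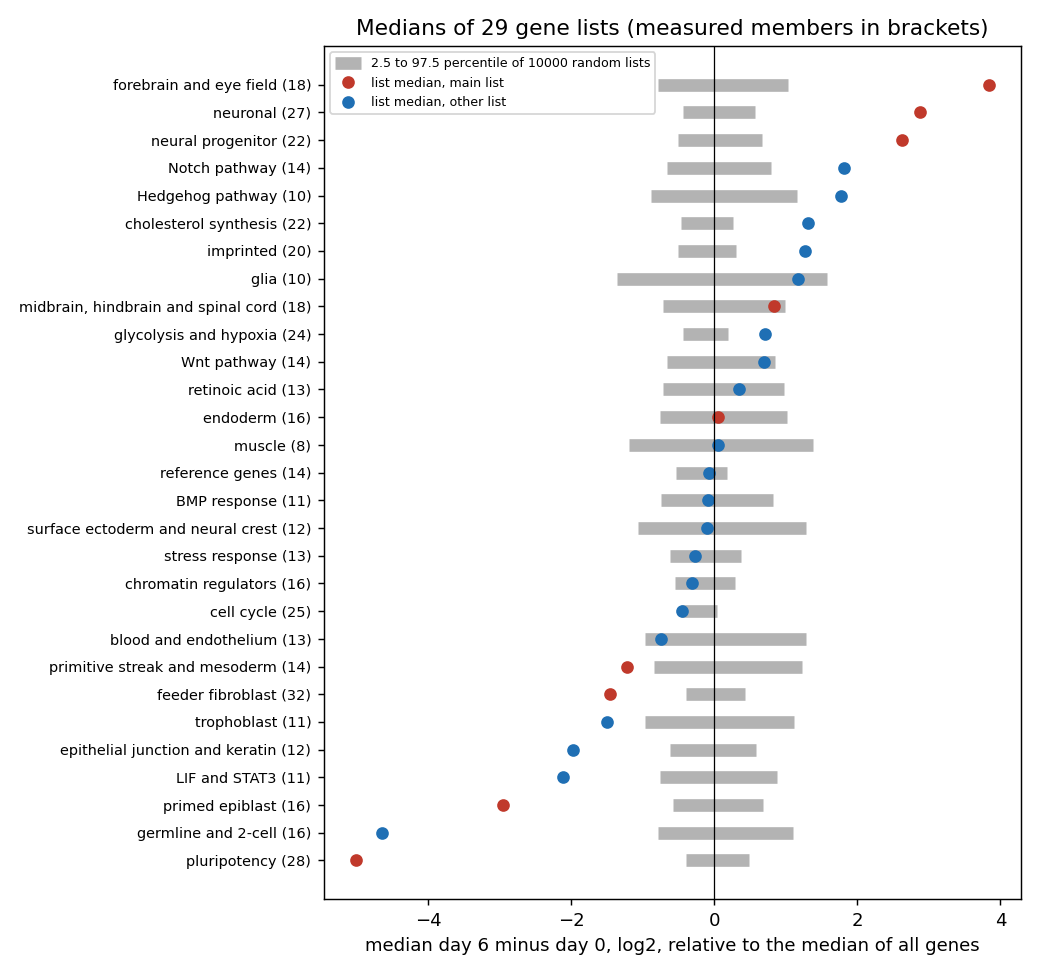
Median log2 difference, day 6 minus day 0, relative to the median of all genes (x axis, log2 units), for all 29 gene lists (y axis, measured members in brackets). Points are list medians, red for main and blue for other lists, and grey bars are the central 95% range of 10000 matched random lists. The forebrain and eye field median of 3.84 and the pluripotency median of -5.02 are the extremes.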

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

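Each group had 1 array, so no replicate could be left out and no samples could be regrouped. The counts of genes stayed within 1.5 times the main counts under every alternative that counted genes. Counting probes, of which 28378 were tested, gave 4977 at least 2-fold higher, 5141 at least 2-fold lower, 1854 at least 4-fold higher and 1885 at least 4-fold lower. Those counts are larger because more items were tested. The share of higher among 2-fold differences was 47.0%, and the lowest share was 41.7%, with median scaling. Median scaling moved the median of all genes to -0.21 from -0.09, and list medians are given relative to that median.

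A list's median was taken to move where it shifted by more than the median software error of its members. The pluripotency, neural progenitor and feeder fibroblast medians moved by less than this under each of their 12 alternatives. The primed epiblast median was -2.45 with normexp, -2.43 with no background subtraction, -1.83 with the filter on both arrays and -2.52 with members at their bound. The forebrain and eye field median was 2.46 with normexp, 2.28 with no background subtraction and 2.83 with members at their bound. The midbrain, hindbrain and spinal cord median was -0.62 with the filter on both arrays, 0.0850 with no filter and 0.16 with the mean of a gene's probes. The neuronal median was 2.63 with normexp, 2.58 with no background subtraction and 2.01 with the filter on both arrays. The primitive streak and mesoderm median was -0.99 with no background subtraction and -0.78 with no filter, and the endoderm median was 0.38 with no filter. The cause was not tested, except that members at their bound and a changed filter use other values or members by construction.

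For the 20 other lists, 30 of 240 medians moved and 0 that lay outside the band changed sign. With unmatched random lists, 3 percentiles crossed the band: 99.1 for midbrain, hindbrain and spinal cord, 99.0 for glia and 2.06 for blood and endothelium. With random lists drawn in each setting, trophoblast came inside the band with normexp, no background subtraction and the filter on both arrays. Wnt pathway came above it with the filter on both arrays, midbrain, hindbrain and spinal cord came above it with members at their bound, and cell cycle came below it with normexp (percentile 2.38). The other lists kept their side. Of the 132 named genes at least 2-fold apart, 0 changed direction, and 9 came under 2-fold in at least 1 setting. Among these, Sox1 stood at 0.91 log2 units with normexp. Signal over background limits genes well above background on 1 array only, where only a bound is known.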

Other observations

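Gene families that share a name stem were described after the data were examined. Of 261 families with at least 8 measured genes, 21 lay above and 22 below the random band. If members varied independently, 13.1 in all would lie outside it. Genes of a name stem can vary together or share only a name, so the excess is not a result about families. Of the 43 families outside the band, 18 came inside it in at least 1 alternative. Of these, 2 (Mrps and Ttc) did so with another random draw alone. Of the families named below, only Ccl came inside, but Lce had a value under 9 of the 10 alternatives only. The protocadherin beta cluster (Pcdhb), neural cell adhesion genes, stood highest. Of 18 measured genes, 14 were at least 2-fold higher on day 6, with a median of 4.15. Under the 10 processing alternatives tried for families, that median lay between 2.37 and 4.34. Pcdhb21 was 43.2-fold higher and Pcdhb22 24.2-fold higher, both well above background on both arrays, and cross-hybridization between these similar genes was not examined. Frizzled receptors (Fzd) were at least 2-fold higher in 7 of 10, with Fzd3 39.4-fold higher, and their median lay between 1.29 and 1.85. Genes of intraflagellar transport (Ift) were at least 2-fold higher in 6 of 14, with a median of 0.98, and 0 were at least 2-fold lower. The families and genes named in this paragraph and the next were chosen after their values were seen.

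The annexins (Anxa) were at least 2-fold lower in 8 of 11 genes, with a median of -2.73 (-2.90 to -1.92 under the alternatives). Anxa8 and Anxa1 were 47.1-fold and 46.4-fold lower. Interferon-inducible genes (Ifi) were at least 2-fold lower in 8 of 9, with a median of -3.19 (-3.19 to -1.25), and Ifi27 was 27.7-fold lower. Chemokine genes (Ccl) were at least 2-fold lower in 8 of 13, with a median of -3.33, and Ccl2 was 51.7-fold lower. Most of the lower Ccl genes were well above background on day 0 only, and the Ccl median was 0.78, inside the band, among the 4 members well above background on both arrays. The median of late cornified envelope genes (Lce) was -4.96 (-5.02 to -2.73 under the 9 alternatives that gave a value), with 6 of 9 at least 2-fold lower, and Lce1i was at least 125-fold lower. Cross-hybridization was not examined here either. On the same arrays 21 of 32 fibroblast genes were at least 2-fold lower on day 6, with a median of -1.46.

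The tests below were written before the values they measure were seen, except the endoderm test. The demand that a share of list members clear its bound by more than its interval was added after the values were seen, and it left the endoderm question open. The forebrain test was altered several times after its values were seen. An interval was first demanded of the gap between the list medians and then not, the gap was then dropped as evidence because it restates the pattern, and a count of members measured on both arrays was added. Genes named below outside the fixed rule were chosen after their values were seen. Intervals are 95% intervals over list members, which are not independent replicates.

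Fibroblast genes were lower on day 6, and feeder cell RNA in the day 0 sample is a candidate explanation. It called for at least 80% of measured members to be at least 2-fold lower. The share was 65.6% (exact interval 46.8% to 81.4%). The prediction also took Xist to be absent from male R1 cells, which was not examined here. Xist had 269 intensity units and was well above background on day 0, and was at least 3.69-fold lower on day 6. Without that check, Xist cannot tell feeder RNA from RNA of the R1 cells. Feeder RNA and lower expression in the cells themselves cannot be told apart. No feeder sample and no feeder-free ES sample was measured, and the interval holds the 80% called for. Of the measured members, 11 were not lower by 2-fold. Among these, Vim, Col3a1, Postn and Mmp2 were not lower, and day 6 cells could express them.

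Forebrain genes were higher while caudal genes went both ways. A shortage of measurable caudal genes was set against this, which called for under 5 measured caudal members. The tables argue against a shortage in number, since 18 were measured. Whether the caudal members were too dim to show a rise was not tested. Of the listed genes, 7 of 25 caudal and 3 of 21 forebrain ones were not well above background on either array. Among measured members, 11 caudal ones were well above background on both arrays against 7 of 18 forebrain ones. That last count depends on the change itself and is no evidence here. The forebrain median exceeded the caudal median by 3.002 log2 units (bootstrap interval 0.96 to 4.88; 1.75 to 4.33 across the alternatives), which describes the pattern and is no evidence on its cause. No biological explanation was tested, nor was feeder RNA as a source of the day 0 signal of caudal genes.

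Foxa2, Foxa1 and Shh were higher on day 6, which may come from endoderm cells in the day 6 sample or from ventral neural tube cells in the day 6 sample. Of 20 other endoderm genes, 4 (20%, exact interval 5.73% to 43.7%) were at least 2-fold higher. That share counts as not higher 6 genes that were not well above background on either array. The ventral share below is of measured genes only, so the shares cannot be compared directly. Afp, Ttr and Apoa1 were not well above background on either array, but Cer1, Cxcr4, Sox17 and Pdgfra were higher, so endoderm cells stay open. Of 10 ventral neural tube genes in a second list, 90% (exact interval 55.5% to 99.7%) were at least 2-fold higher. Among these, Ferd3l (at least 2.03-fold) and Sulf1 (2.08-fold) passed the cut only narrowly. Spon1 was at least 95.6-fold higher and Nkx2-2 18.1-fold higher, which is consistent with ventral neural tube cells as a hypothesis.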
